A study of Caenorhabditis elegans with 12 samples.

How the data were processed

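The study sequenced polyadenylated RNA of whole N2 worms after RNAi of y54g2a.18 or rpoa-49 and after a control RNAi for each, with 3 libraries per group, on an Illumina NovaSeq, per the labels' protocols. The authors deposited raw counts per gene, one table per experiment and one column per library, with no normalization. FastQC 0.11.9, HISAT2 2.2.1, featureCounts 1.28.1 and DESeq2 1.16.1 are named without role or order, per the submitters' processing notes. The genome build, the gene annotation, the strand setting and the handling of reads that fit several genes are not given in the sources used here. Groups and replicate numbers were taken from the sample titles, and each column was matched to its sample by the library name in the labels. One title and one protocol spell a target slightly differently (y54g21.18, rpoa-40), and both were read as the gene named in the series.

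The y54g2a.18 table had 46903 entries, 12 of which carried dates in place of gene names and were left out (at most 0.0247% of the counts of a library). Of the other names, 99.9% matched a RefSeq symbol or sequence name of the assembly WBcel235. That reference was used only for names, neighbours, overlaps and transcript numbers, and no coordinates are given because the authors' build is unknown. Low counts were mostly even: of values from 1 to 20, 71.5% were even in the y54g2a.18 table and 100% in the rpoa-49 table, as when both mates of a read pair are counted. Counting intervals and floors are therefore too narrow, and they cover counting error only. Floors are 3 counts over the 3 libraries of a group, and counting intervals are exact (Clopper-Pearson) at 95%. Libraries of a group were compared before averaging. Their log CPM correlated at 0.986 to 0.991 in the controls and 0.965 to 0.974 in the knockdown, and chi-square per degree of freedom was 22.7 to 171, so no library was a duplicate of another.

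Tests were run in R 4.3.3 on the 6 libraries of the y54g2a.18 experiment alone. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by trimmed means (TMM), and edgeR 4.0.16 fitted a quasi-likelihood model with the group as its only term, with Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p of 0.05. CPM values are TMM-scaled and log2 fold changes are those of the fit, RNAi minus control. Standard errors were derived as the absolute log2 fold change divided by the square root of the F statistic of the quasi-likelihood test, so they are approximate. Before the data were examined, 34 gene lists were fixed, and they were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 and again with an estimated correlation, Benjamini-Hochberg adjusted over the lists. Families by symbol prefix with at least 10 tested genes were tested in the same way. Of the list members 12 were not found, and the 12 mitochondrial genes were matched through the reference tables after the table was seen, because it names them differently. List members at 0 or at low counts were not tested.

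The genes to name were fixed by rule: both targets; the 8 called genes with the highest and the 8 with the lowest log2 fold change whose groups do not overlap and whose higher group has a mean of at least 10 CPM; the 3 called members with the smallest p of each passing list; and those of the 3 families with the smallest camera p. Other genes in the text were chosen after their values were seen, as were the bound of 16-fold for collagens, the set of genes with at most 3 counts in a group and the bound of 8-fold for adjacent genes.

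Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, total counts, upper-quartile factors, no filter, at least 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were the log ribosomal RNA share as a covariate, leaving out ribosomal RNA genes, keeping only genes with 1 RefSeq transcript, and the list alternatives for families.

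The steps were tested on simulated data made from the means, dispersions and library sizes of the y54g2a.18 experiment over 14112 genes, with 50 genes changed at each of 4 sizes. At 1.5-, 2-, 4- and 8-fold, 0%, 28%, 76% and 98% of the changed genes were recovered, none in the wrong direction. Of 115 calls 14 were false, more than the nominal 5% at this threshold. In the list test the raised set passed and 0 of 33 unchanged sets did, with genes simulated as independent.

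The rpoa-49 table could not be tested. It held 43236 names in the style of human genes and 418 counts in all, and 0.0278% of its names occur in the y54g2a.18 table. The planned comparisons of rpoa-49 RNAi with its control, of the knockdowns with each other, and a fit of all 12 libraries were not run for that reason.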

Results

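Polyadenylated RNA was sequenced from whole Caenorhabditis elegans of the wild-type N2 strain after RNA interference (RNAi), in which double-stranded RNA lowers the transcript of a chosen gene. The targets were y54g2a.18, the worm homologue of the endoplasmic reticulum (ER) membrane protein gene BCAP31, and rpoa-49, the homologue of the RNA polymerase I subunit gene POLR1E. The question of the series was how these genes influence the ageing of the worm. Each knockdown had its own RNAi control, with 3 libraries in each of the 4 groups and 12 libraries in all. The age and stage of the worms are not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. In the y54g2a.18 experiment the control libraries held 38919451, 39492584 and 34561881 counts and the knockdown libraries 37336711, 38313344 and 30103422. Ribosomal RNA made up 1.03, 1.64 and 0.214% of the control counts and 0.0937, 1.31 and 2.02% of the knockdown counts. The first principal component of log CPM (counts scaled to library size) carried 53.7% of the variance and separated the knockdown libraries from the controls, and the second, with 22.2%, spread the libraries within each group.

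The first comparison was of the targeted gene itself, as a check of the labels. Y54G2A.18 fell from 386 ± 25.9 CPM in the controls to 136 ± 50.5 CPM in the knockdown (SD, n = 3 in each group), which is 2.84-fold lower. The log2 fold change was -1.51 with a standard error of 0.25 and an adjusted p of 0.0073 by edgeR's quasi-likelihood test. Single libraries held 391, 358 and 409 CPM in the controls and 190, 128 and 90.2 CPM in the knockdown, so each knockdown library lay below each control library. Y54G2A.18 overlaps dib-1, and strand-specific counting is not given in the sources used here, so reads of the overlap cannot be assigned to either gene. The counts of dib-1 were 167 ± 17.1 CPM in the controls and 139 ± 25.4 CPM in the knockdown (adjusted p = 0.40). The other targeted gene of the series, rpoa-49, was at 29.3 ± 1.43 CPM in the controls and 30.7 ± 2.89 CPM after y54g2a.18 RNAi (adjusted p = 0.84).

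**Figure D1:**
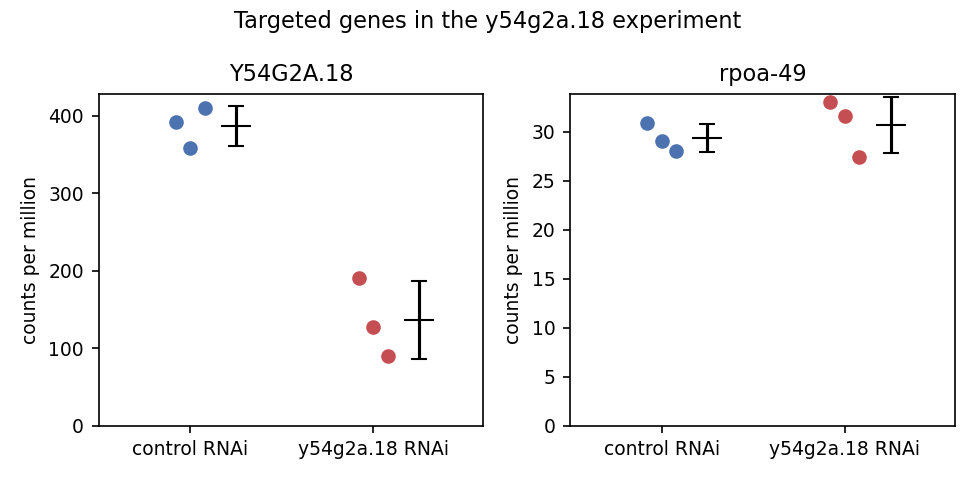
CPM (vertical axes, starting at 0) of Y54G2A.18 on the left and rpoa-49 on the right in the 3 control and 3 y54g2a.18 RNAi libraries of the y54g2a.18 experiment. Points are libraries and the bars show mean and SD; Y54G2A.18 lies between 90.2 and 190 CPM after knockdown and between 358 and 409 CPM in the controls, whereas the rpoa-49 points of both groups overlap.

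Among genes with at least 10 CPM in a group, several of the strongest rises after y54g2a.18 RNAi were in cuticle collagens, which form the outer covering of the worm. col-36 rose from 2.9 ± 0.68 to 327 ± 223 CPM, col-158 from 1.35 ± 0.17 to 217 ± 177 CPM and col-43 from 1.2 ± 0.20 to 175 ± 115 CPM (SD, n = 3 in each group). The log2 fold changes of these genes were 6.82, 7.33 and 7.23, with standard errors of 0.71, 0.84 and 0.68. col-114 rose from 0.081 to 22.7 CPM and col-164 from 0.108 to 13.7 CPM. Outside the collagens, grl-19, a hedgehog-related gene of the ground-like family, rose from 0.068 to 15 CPM and C13A2.9 from 0.097 ± 0.13 to 13.1 ± 9.44 CPM. The sizes of some of these rises depended on single libraries. The log2 fold change of C13A2.9, 7.12, was 6.5 and 8.82 without control replicates 2 and 3 and 6.47 without knockdown replicate 3, and without that library those of col-158, col-164 and grl-19 were 6.58, 6.28 and 7.04, against 7.33, 6.95 and 7.65. C33G8.13 had 0, 1 and 2 counts in the control libraries and 461, 101 and 663 in the knockdown libraries, a ratio of 430 with a 95% counting interval of 147 to 2088, and its fitted log2 fold change of 8.62 became 9.54 without control replicate 3 and 7.98 without knockdown replicate 3. Among the genes that fell most, C02E7.10 went from 42.0 ± 5.11 to 2.97 ± 1.74 CPM, 14.2-fold lower, and R02C2.7 from 101 ± 6.23 to 11.7 ± 1.90 CPM, 8.66-fold lower. C17F4.3 and C17F4.12 were 6.73- and 7.09-fold lower, T26E4.4 was 7.0-fold lower, srlf-4 6.49-fold, oac-30 6.36-fold and T13C5.3 6.17-fold. The adjusted p of these 16 genes ranged from 0.000307 for R02C2.7 to 0.00383 for grl-19 in edgeR. The call of grl-19 was lost in limma-voom (adjusted p = 0.088).

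In all, 1283 of 14290 tested genes (8.98%) passed an adjusted p of 0.05 in edgeR, 567 of them higher and 716 lower after y54g2a.18 RNAi. Of these, 379 were at least 2-fold higher and 589 at least 2-fold lower. Before adjustment, 3324 of the 14290 tested genes had a p under 0.05 in edgeR. Counts of unadjusted p in the lists below are to be read against that share of all genes. The 3 knockdown libraries lay on one side of all 3 control libraries for 4346 tested genes (30.4%), where chance gives 10% on average. Genes vary together, so this share can lie far from 10% by chance, and it was not computed for other groupings of the libraries. The number of calls depended on single libraries: it was 646, 664 and 667 without control replicate 1, 2 or 3 and 2097 without knockdown replicate 1. With the log share of ribosomal RNA as a covariate, an alternative chosen after seeing the data, 2214 genes were called, among them all 1283. Of 34 gene lists fixed before the data were examined, 8 passed limma's camera test, 4 higher and 4 lower. Without knockdown replicate 2 the number was 4 and with an estimated correlation 0, and the other splits of the same 6 libraries into 3 and 3 passed 5 to 15 lists.

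Cuticle collagens changed in both directions. Of 128 tested members of a list fixed before the data were examined, 22 rose and 45 fell over all genes tested, and 26 rose and 55 fell adjusted over the list alone; over the 17 alternatives 19 to 24 rose and 31 to 68 fell. A set of 17 rose by more than 16-fold, a bound chosen after the values were seen. Their fitted log2 fold changes ran from 4.2 to 8.08 for the 16 with counts in the controls, while col-163, with 0 counts in all controls and 192 in the knockdown, was at least 67.4-fold higher (against 3 counts over the group), a limit that falls to 42.3 without knockdown replicate 3. Summed over the 17 genes, expression was 17.2 ± 1.66 CPM in the controls and 1282 ± 878 CPM in the knockdown. The knockdown sums were 1587, 292 and 1966 CPM, and replicate 2 was the lowest. The 45 collagens that fell had fold changes from -2.15 to -0.94 on the log2 scale and summed to 14630 ± 1357 CPM in the controls and 5117 ± 1108 CPM in the knockdown. Among them, col-131 fell from 239 ± 22.4 to 61.9 ± 4.13 CPM and col-156 from 70.6 ± 5.76 to 21.7 ± 1.47 CPM, while col-89 rose from 20.3 ± 1.21 to 94.9 ± 13.7 CPM. The list passed limma's camera test as lower (adjusted p = 1.6e-05) with a median log2 fold change of -0.68 (-1.06 without knockdown replicate 1) and a mean of 0.18, which differ in sign. It did not pass with an estimated correlation (adjusted p = 0.992) or without knockdown replicate 2 (adjusted p = 0.438). Collagen genes resemble one another, and how the authors' counting treated reads shared between them is not given in the sources used here, so single values are uncertain to that extent.

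**Figure D2:**
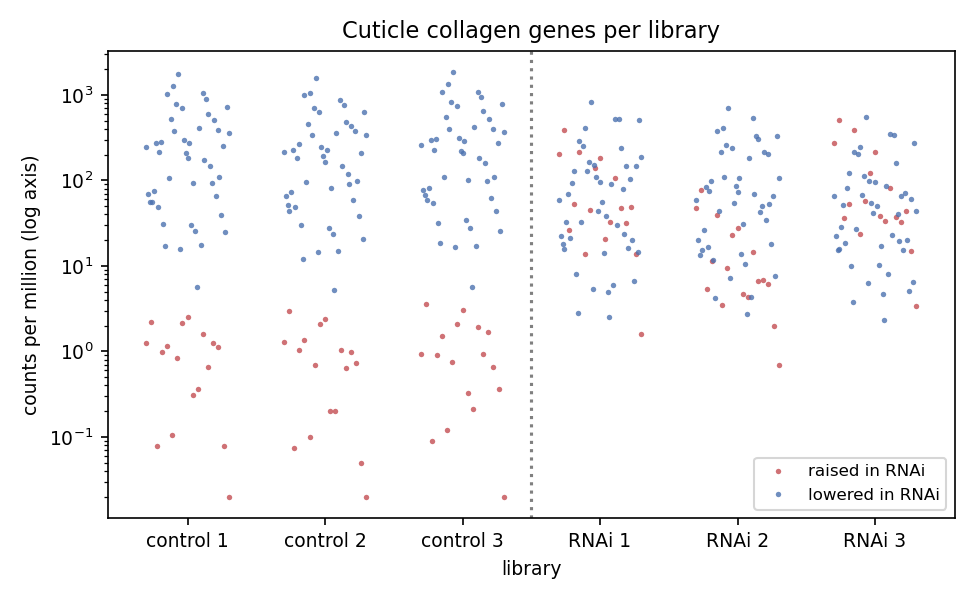
CPM (vertical log axis) of the 17 collagen genes that rose by more than 16-fold (red) and the 45 that fell (blue) in each of the 6 libraries of the y54g2a.18 experiment (horizontal axis); each point is a gene, sideways offsets only separate points, and values of 0 are drawn at 0.02. The red points lie at or below a few CPM in the controls (sum 17.2 CPM) and mix with the blue points after knockdown (sum 1282 CPM).

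Genes of the molting cycle, in which the cuticle is replaced, were called lower more often than higher. Of 14 tested members 6 fell and 2 rose, and 9 fell and 2 rose adjusted over the list alone; over the 17 alternatives 4 to 9 fell and 0 to 2 rose. mlt-8 fell from 312 ± 18.1 to 109 ± 18.8 CPM, and the hedgehog-related genes wrt-1 and wrt-10 fell from 105 ± 5.53 to 29.9 ± 10.6 CPM and from 158 ± 2.70 to 47.6 ± 17.4 CPM (SD, n = 3). The members that rose, named after their values were seen, were nekl-3 (log2 0.80, adjusted p = 0.021) and grd-3 (log2 0.72, adjusted p = 0.027). Both of these calls were lost without any one control library, with adjusted p up to 0.133 and 0.149, and that of grd-3 also without knockdown replicate 2 (0.0536). The median log2 fold change of the list was -1.23, and camera gave an adjusted p of 0.000127, against an adjusted p of 0.486 with an estimated correlation.

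The intracellular pathogen response, a set of genes switched on by microsporidia and viruses, was higher. Of 12 tested members 6 rose and 0 fell in edgeR, 9 members had an unadjusted p under 0.05, and 8 rose adjusted over the list alone; DESeq2 called 7 and limma-voom 6, and over the 17 alternatives 3 to 8 rose. pals-39 rose from 11.7 ± 1.03 to 33 ± 8.19 CPM, pals-14 from 2.34 ± 0.56 to 7.87 ± 2.04 CPM and pals-6 from 1.34 ± 0.051 to 3.79 ± 0.82 CPM (SD, n = 3). skr-5, which encodes a Skp1-related protein of ubiquitin ligases, rose from 15 to 36.5 CPM (adjusted p = 0.0087, but 0.0569 and 0.0502 without control replicates 1 and 2). The regulators pals-22 and pals-25 of this response were at 19.4 and 15 CPM in the controls and 19.6 and 15.4 CPM in the knockdown (adjusted p = 0.97 and 0.92). skr-5, pals-22 and pals-25 were chosen after their values were seen. The list had a median log2 fold change of 1.45 and a camera adjusted p of 1.23e-06, against an adjusted p of 0.486 with an estimated correlation.

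Antimicrobial and pathogen response genes were higher more often than lower. Of 26 tested members 8 rose and 2 fell, and 11 rose and 3 fell adjusted over the list alone; over the 17 alternatives 4 to 11 rose and 0 to 3 fell. The lysozyme gene lys-3 rose from 32.2 ± 0.49 to 107 ± 18.7 CPM, the antimicrobial peptide gene cnc-4 from 81.5 ± 4.94 to 185 ± 19 CPM and the flavin monooxygenase gene fmo-2 from 60.8 ± 2.66 to 142 ± 35.0 CPM (SD, n = 3). The members that fell, named after their values were seen, were the lysozyme genes lys-8 (log2 -0.58, adjusted p = 0.023) and ilys-2 (log2 -0.94, adjusted p = 0.046), and both calls were lost with upper-quartile scaling and without any one control library, with adjusted p up to 0.162 and 0.175, and that of ilys-2 also without knockdown replicate 3 (0.0698). The median log2 fold change was 0.42 and the camera adjusted p 0.00203, against an adjusted p of 0.486 with an estimated correlation.

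Among ER chaperones and genes of the unfolded protein response 3 of 20 tested members rose, 0 fell in edgeR, and the same numbers were found adjusted over the list alone. DESeq2 called 3 members, limma-voom 2, and the 17 alternatives 1 to 6. An unadjusted p under 0.05 was found for 5 of the 20, against 3324 of all 14290 tested genes. ckb-2, a choline kinase gene induced by ER stress, rose 8.56-fold from 11.7 ± 0.57 to 99.9 ± 28.2 CPM. hsp-4, which encodes the ER chaperone BiP, rose from 90.4 ± 5.63 to 205 ± 64.3 CPM, and dnj-27, an ER J-domain protein gene, from 7.61 ± 1.00 to 16 ± 5.83 CPM (SD, n = 3). The adjusted p of hsp-4 was 0.014, and its call was lost without any one control library (adjusted p up to 0.0754). The adjusted p of dnj-27 was 0.047, and its call was lost in 8 of 16 alternatives, limma-voom and the omission of any one control library or of knockdown replicate 2 or 3 among them, with adjusted p up to 0.178. The median of the list was 0.24 on the log2 scale (0.48 without knockdown replicate 1), with a camera adjusted p of 0.0125. The list did not pass without knockdown replicate 2 (median 0.09, adjusted p = 0.349) or with an estimated correlation (adjusted p = 0.992).

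SKN-1 targets and glutathione detoxification genes had 2 lower and 0 higher members in edgeR among 14 tested, also adjusted over the list alone; 6 had an unadjusted p under 0.05, and DESeq2 and limma-voom each called 2, and the 17 alternatives 2 or 3. The glutathione S-transferase gene gst-19 fell 4.37-fold from 25.3 ± 2.74 to 5.79 ± 0.72 CPM and sdz-8 fell 2.24-fold from 53.2 ± 3.97 to 23.7 ± 5.74 CPM (SD, n = 3). The widely used SKN-1 target gst-4 was at 42.0 CPM in the controls and 40.5 CPM in the knockdown (adjusted p = 0.88). The median log2 fold change was -0.29 and the camera adjusted p 0.0188, which became 0.0584 without knockdown replicate 2, and the adjusted p was 0.486 with an estimated correlation.

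Sperm genes had a higher median and oocyte genes a lower one, with few single calls. Of 79 tested major sperm protein and sperm genes, 1 rose and 0 fell in edgeR, 0 were called adjusted over the list alone, 23 had an unadjusted p under 0.05, and DESeq2 called 7 and limma-voom 1. edgeR called 3 higher with total counts, 6 without knockdown replicate 3 and 19 with the ribosomal RNA covariate, and 0 without any one control library. The called gene, spe-12, needed for sperm activation, was at 1.31 ± 0.20 CPM in the controls and 3.12 ± 0.82 CPM in the knockdown (adjusted p = 0.024, and up to 0.127 without any one control library or knockdown replicate 3). The median of the list was 0.50 on the log2 scale and its camera adjusted p 0.000127; without knockdown replicate 1 the median was 0.22 and the adjusted p 0.0637, and with an estimated correlation the adjusted p was 0.992. Of 26 oocyte and germline genes 0 were called in edgeR, over all genes or adjusted over the list alone, as in DESeq2 and limma-voom, and 5 had an unadjusted p under 0.05; edgeR called 5 lower without knockdown replicate 1 and 3 with the ribosomal RNA covariate. Their median was -0.31 with a camera adjusted p of 0.0245, which became 0.0863 without control replicate 2, 0.147 without knockdown replicate 2 (median -0.21) and 0.698 with an estimated correlation. The 5 tested vitellogenin genes, which encode yolk proteins, varied widely within groups. vit-2 stood at 2525, 4075 and 1633 CPM in the controls and 553, 1234 and 5519 CPM in the knockdown, and in each group the library with the most ribosomal RNA had the highest vit-2 value. No vitellogenin was called in edgeR, DESeq2 or limma-voom, 0 had an unadjusted p under 0.05, and the list had a median of 0.40 (camera adjusted p = 0.84), which ran from -0.51 without knockdown replicate 3 (adjusted p = 0.563) to 0.74 without knockdown replicate 2.

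**Figure D3:**
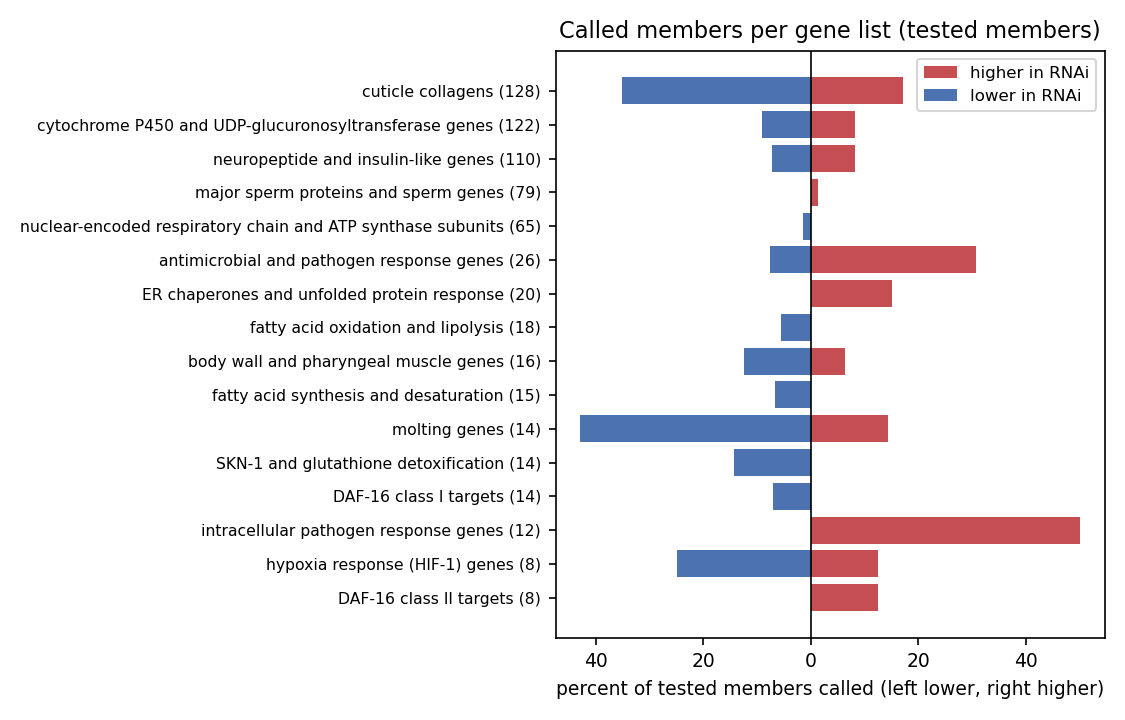
Percent of the tested members of each gene list that were called higher (right, red) or lower (left, blue) after y54g2a.18 RNAi by edgeR at an adjusted p of 0.05, for the lists with at least 1 called member; numbers in brackets are tested members. Molting genes and cuticle collagens hold the highest shares of lower calls (6 of 14 and 45 of 128), and intracellular pathogen response genes the highest share of higher calls (6 of 12).

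Several lists with called members did not pass the camera test. Cytochrome P450 and UDP-glucuronosyltransferase genes, which modify foreign compounds, had 10 higher and 11 lower of 122 tested (14 and 13 adjusted over the list alone; adjusted p = 0.866). cyp-34A7 fell from 7.90 to 2.03 CPM and cyp-29A3 from 2.59 to 0.45 CPM. Neuropeptide and insulin-like genes were taken by the symbols flp, nlp and ins and not by function, and nlp-29 and nlp-31 are also in the antimicrobial list. This list had 9 higher and 8 lower of 110 (11 and 8 adjusted over the list alone; adjusted p = 0.454, and 0.0254 without knockdown replicate 3), and 10 higher and 4 lower with upper-quartile scaling. nlp-27 rose from 437 to 1100 CPM and ins-20 from 0.52 ± 0.30 to 7.01 ± 4.70 CPM (log2 3.73, and 3.05 without knockdown replicate 1). DAF-16 class I targets, which insulin signalling represses, had 1 lower of 14 (also adjusted over the list alone; adjusted p = 0.989), the fatty acid desaturase gene fat-5. fat-5 fell from 318 to 159 CPM (adjusted p = 0.014, and 0.068 and 0.0691 without control replicates 1 and 3) and was also the only call among 15 fatty acid synthesis genes (list adjusted p = 0.84). sod-3, a much used reporter of DAF-16, was at 15.9 ± 2.77 CPM in the controls and 25.5 ± 8.19 CPM in the knockdown (adjusted p = 0.15). DAF-16 class II targets had 1 higher of 8, dod-24, at 10.2 and 31.8 CPM, with 3 adjusted over the list alone (list adjusted p = 0.264, and 0.0436 without knockdown replicate 1). Among 18 fatty acid oxidation genes only acdh-1 was called, lower at 365 and 175 CPM (list adjusted p = 0.842). acdh-1 has 2 RefSeq transcripts, so its counts may be incomplete, as stated for hsp-4 and dnj-27. Among 65 nuclear genes of the respiratory chain only sdha-2 was called, lower by 0.56 on the log2 scale with an adjusted p of 0.026 that was lost with upper-quartile scaling (0.0662), without any one control library (up to 0.178) and without knockdown replicate 3 (0.064). Over that list alone 0 were called, where 5 had an unadjusted p under 0.05 and DESeq2 and limma-voom each called 1 over all genes (list adjusted p = 0.293, and 0.0251 without knockdown replicate 1). Muscle genes had 1 higher and 2 lower of 16, the troponin genes tnt-2 (log2 0.85), tnc-2 (log2 -1.30) and tni-4 (log2 -0.72), and the calls of tnt-2 and tni-4 were lost without any one control library (adjusted p up to 0.127 and 0.1; list adjusted p = 0.989). Hypoxia response genes had cysl-2 higher (43.3 and 90.4 CPM) and gst-19 and F22B5.4 lower among 8, with 2 higher and 3 lower adjusted over the list alone (list adjusted p = 0.293). Members outside the rule for named genes were picked after their values were seen. For the DAF-16 class I, P450 and fatty acid oxidation lists, the camera direction was lower although the median was above 0 (0.08, 0.03 and 0.12), and that of the P450 list turned below 0 in at least 1 alternative (lowest -0.0187). Each of these 3 medians moved by more than 1.5 times when some single libraries were left out. Over the 17 alternatives the calls ran from 0 to 18 higher and 4 to 15 lower for the P450 list and from 5 to 14 higher and 2 to 9 lower for the neuropeptide list, with the lowest numbers when a control library was left out. For DAF-16 class I targets and fatty acid oxidation they ran from 0 to 2 in either direction, for class II from 1 to 3 higher, for fatty acid synthesis from 0 to 1 lower and for the respiratory chain from 0 to 5 lower. Muscle genes had 0 to 3 higher and 1 to 3 lower, and hypoxia genes 1 higher and 2 or 3 lower.

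The remaining 17 lists held 304 tested genes, vitellogenins included, of which edgeR called 0, while 14 had an unadjusted p under 0.05, DESeq2 called 2 (hsp-16.41 lower, asp-3 higher) and limma-voom 1 (hsp-16.41). edgeR called 1 heat shock gene lower with total counts. Over the 17 alternatives at most 4 neuronal, 3 intestinal and 2 autophagy genes were called higher, at most 3 proteasome genes lower, these numbers all without knockdown replicate 1, and at most 1 gene per direction in each of the other lists. In camera, proteasome subunits had an adjusted p of 0.163 with a median log2 fold change of -0.17, mitochondrially encoded genes 0.368 with -0.19, neuronal genes 0.37 with 0.30 and intestinal genes 0.436 with 0.21. Early embryonic genes gave 0.454 with a median of 0.87 over 5 tested genes, and autophagy genes 0.653 with 0.10. DNA replication and cell cycle genes gave 0.653 with -0.12, the RNA interference machinery 0.653 with -0.13, cytosolic ribosomal proteins 0.667 with -0.04 and the mitochondrial unfolded protein response 0.819 with -0.04. Apoptosis genes gave 0.819 with -0.19, cytosolic heat shock genes 0.84 with 0.12, nucleolar and ribosome biogenesis factors 0.866 with -0.05, and RNA polymerase I and III subunits 0.872 with -0.05. ER-associated degradation genes gave 0.989 with a median of 0.02, and longevity regulators 0.989 with 0.06. Without knockdown replicate 1, neuronal genes (adjusted p = 0.0232) and proteasome subunits (adjusted p = 0.0303) passed. The median of the ribosomal proteins was above 0 with upper-quartile scaling, and the medians of heat shock, ER-associated degradation, nucleolar, RNA polymerase, ribosomal protein, autophagy, apoptosis and longevity genes changed sign in at least 1 alternative. All medians in this paragraph but those of intestinal and early embryonic genes moved by more than 1.5 times without at least 1 of the libraries. Of the 22 longevity regulators 10, daf-16 and daf-2 among them, were listed at 0 in all libraries and were not tested. Other genes with several transcripts were also often at 0. Of protein-coding genes with 1 RefSeq transcript 6.9% were at 0 in all 6 libraries, against 39% with 2, 53.0% with 3 and 76.3% with 6 or more, so a value of 0 for such a gene does not show that it was not expressed.

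**Figure D4:**
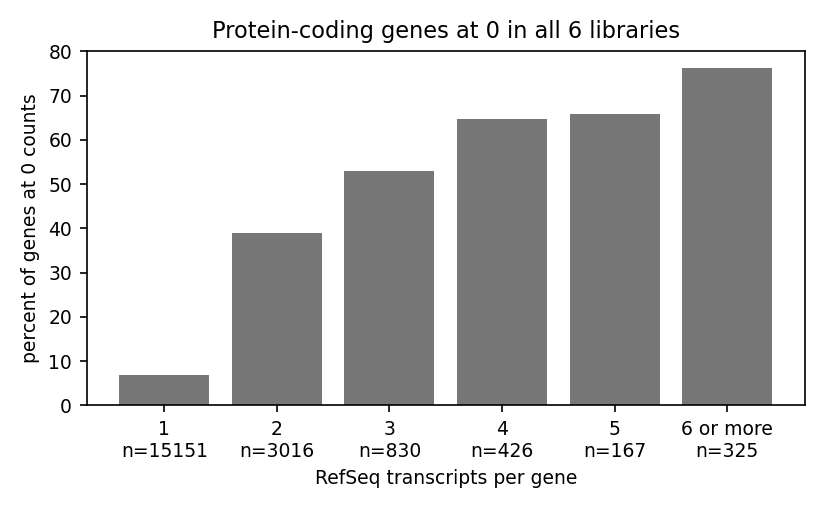
Percent of protein-coding genes with 0 counts in all 6 libraries of the y54g2a.18 experiment (vertical axis, starting at 0) by the number of RefSeq transcripts of the gene (horizontal axis, with the number of genes). Each bar is the share over all genes of that class, without replicate error because the libraries are pooled; it rises from 6.9% with 1 transcript to 76.3% with 6 or more.

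Gene families by symbol prefix gave 12 passing camera among 129, 4 higher and 8 lower, and 0 with an estimated correlation (adjusted p = 0.987 for each). Without knockdown replicate 1 the number was 20, and the other splits of the 6 libraries passed 12 to 40 families. Of 17 nspc genes, which encode nematode-specific peptides, 11 rose, nspc-13 from 7.88 ± 0.72 to 31.4 ± 8.48 CPM, nspc-14 from 28.6 ± 1.84 to 64.4 ± 10.3 CPM and nspc-9 from 16.7 ± 2.28 to 46.5 ± 10.4 CPM (SD, n = 3). Of 26 pals genes 8 rose, pals-4 from 1.15 ± 0.11 to 5.51 ± 1.68 CPM and pals-28 from 0.34 ± 0.13 to 2.80 ± 0.71 CPM. Of 19 dpy genes, mutants of which are short and stout, 8 fell and 1 rose. Among those that fell were the collagens dpy-5, from 1222 ± 146 to 357 ± 93.0 CPM, and dpy-2, from 210 ± 13.5 to 57.3 ± 25.1 CPM, and dpy-20, from 17.7 ± 1.73 to 4.57 ± 1.47 CPM. The oac, idpp, wrt, bath, srlf, col and fipr families were lower and the msp and ttr families higher, with 0 of 30 msp genes called in edgeR. For the col family, most of the collagen list, the median was -0.51 (-0.99 and -0.29 without knockdown replicates 1 and 3) and the mean 0.38. It did not pass without control replicate 3 (adjusted p = 0.0506) or knockdown replicate 3 (0.0948), and without knockdown replicate 2 the camera direction turned (adjusted p = 0.51). The fipr family did not pass without knockdown replicate 2, the msp and ttr families without knockdown replicate 1, and ttr without control replicate 2. Single values in these families of similar genes are uncertain where reads were shared.

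The effect of rpoa-49 RNAi could not be measured from the counts of that experiment. The table for its 6 libraries held names in the style of human genes, of which 12, all mitochondrial, were shared with the names of the y54g2a.18 table. In all, 162 names had any count, with 418 counts in total, the libraries held 72, 76 and 76 counts in the controls and 62, 38 and 94 after rpoa-49 RNAi, and the largest single value was 10. No name in it was rpoa-49, and POLR1E, BCAP31, ACTB and GAPDH were at 0 in all 6 libraries. No comparison of rpoa-49 RNAi with its control, and none between the knockdowns, was therefore made.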

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

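The ribosomal RNA covariate, the omission of ribosomal RNA genes, the restriction to genes with 1 RefSeq transcript and the alternatives for families were chosen after seeing the data. The number of called genes, 1283, ran from 955 to 1772 over the other scalings, filters, tools and the block, but from 646 to 2097 when single libraries were left out and to 2214 with the ribosomal RNA covariate; the cause was not tested. The log2 fold change of Y54G2A.18 ran from -1.83 to -1.28 and stayed called in all 10 alternatives run for it (adjusted p from 1.32e-06 to 0.0331). The number of passing lists, 8, ran from 4 to 11 without single libraries and was 0 with an estimated correlation, which sets how far the genes of a list move together; that of families, 12, ran from 11 to 20 and was 0. The col family turned in camera direction without knockdown replicate 2 (median -0.381 on the log2 scale, adjusted p = 0.51; medians ran from -0.989 to -0.285 without single libraries). Of 43 named genes beside the target, 39 kept their side of the threshold in every alternative, and grl-19, hsp-4, dnj-27 and spe-12 lost their call in some; none turned in direction. Same-numbered libraries did not deviate together (r = 0.0074, 0.0454 and -0.365), while differently numbered ones ran from -0.418 to 0.403. This gives no sign that the numbers pair them, but so few libraries cannot exclude a smaller shared effect. A replicate block gave 955 calls, 8 lists and 11 families (the col family was lost, adjusted p = 0.211) and kept Y54G2A.18 called at -1.57. Among the named genes the block ended the calls of dnj-27 and spe-12. Among other genes in the text it ended those of sdha-2 (adjusted p = 0.104), lys-8 (0.093), ilys-2 (0.0916), nekl-3 (0.0761), Y54G2A.50 (0.0722), grd-3 (0.0709), tnt-2 (0.0548), tni-4 (0.0539) and nlp-28 (0.0519), while col-7 (0.0249) and col-62 (0.0283) became called. The fit of all 12 libraries and every alternative for rpoa-49 RNAi were not run. In the simulated data, effects of 2-fold or less were mostly missed. That simulation gave 115 calls in all, against 1283 in the real data, so its recovery rates may not hold for the real data. Its library sizes were not varied, so whether depth set this limit was not tested.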

Other observations

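The tests on essential genes at 0, on the other collagens, on the ribosomal RNA covariate, on developmental stage, on library totals, on chromosome stretches, on sequence differences and on splits for called genes were chosen only after the data or the result were seen, as were the genes, sets and bounds below. The caenacin gene cnc-1, which encodes an antimicrobial peptide and is a member of none of the lists, rose 27-fold, from 0.84 ± 0.25 to 22.8 ± 5.59 CPM (SD, n = 3, adjusted p = 0.00044 in edgeR). Of the 8 genes nlp-27 to nlp-34 of the neuropeptide list, 6 were called higher, 1 lower and 1 was not called, and no test was made of them as a group. These 6 make up most of the 9 higher calls of that list. Among them, nlp-29 and nlp-31 are counted in the antimicrobial list too. nlp-27, nlp-32 and nlp-34 rose 2.52-, 5.62- and 2.73-fold, and these 3 and cnc-1 were called in all 17 alternatives. nlp-28 (log2 0.80, adjusted p = 0.034) and nlp-29 (log2 0.76, adjusted p = 0.023) lost their calls without any one control library (adjusted p up to 0.162 and 0.156), nlp-28 also without knockdown replicate 3, and nlp-31 (log2 1.05, adjusted p = 0.0066) without control replicate 1 (0.0521). nlp-33 fell from 223 ± 33.6 to 111 ± 26.7 CPM (adjusted p = 0.016, and 0.0648 and 0.0783 without control replicates 2 and 3), and nlp-30 was at 27.9 ± 3.62 and 32.7 ± 7.29 CPM (adjusted p = 0.55). cut-1, which encodes a cuticle component of dauer larvae, rose from 0.16 ± 0.11 to 13.7 ± 14 CPM (log2 6.38, and 5.15 without knockdown replicate 3; adjusted p = 0.0060, but 0.0722 in limma-voom), and the collagens col-2 and col-40, known from dauer larvae, rose 53.7- and 44.7-fold. No set of dauer genes was tested. Of other genes looked at, hil-1, hsp-12.6 and ctl-1 were not called in edgeR (log2 0.07, 0.38 and 0.61, adjusted p = 0.825, 0.41 and 0.335). Over the alternatives the adjusted p of hsp-12.6 went as low as 0.022. The adult collagens col-7 and col-62 were at 28.7 ± 0.96 and 21.4 ± 1.85 CPM in the controls and 6.01 ± 6.37 and 7.61 ± 6.19 CPM in the knockdown (log2 -2.25 and -1.49, adjusted p = 0.079 and 0.10 in edgeR). The collagens col-19, col-119, bli-1 and bli-2, looked at beside them, were at 0 in all libraries, controls included, and could not be compared. limma-voom (adjusted p = 0.0227 and 0.0437) and edgeR with the ribosomal RNA covariate (0.0028 and 0.00462) called col-7 and col-62 lower, DESeq2 called only col-62 (0.0081, against 0.074 for col-7), and edgeR without a filter only col-7 (0.0279, against 0.0512 for col-62). Without knockdown replicate 1 both were called, at log2 -3.58 and -2.40 (adjusted p = 0.00128 and 0.000747), and over all alternatives adjusted p reached 0.2 and 0.246.

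Only 2 runs of at least 4 adjacent tested genes were called in one direction by more than 8-fold. C13A2.12, C13A2.9, C13A2.6, C13A2.5 and C13A2.4 were all higher; C13A2.12 rose from 3.31 ± 0.23 to 194 ± 152 CPM, and C13A2.4 went from 0 counts in every control to 218, 51 and 333, at least 211-fold higher (135-fold without knockdown replicate 3). The call of C13A2.5 was lost without control replicate 2 or 3 (adjusted p up to 0.055). Their tested neighbours C05C8.8 and C13A2.3 had log2 fold changes of 1.09 and -0.29 (adjusted p = 0.264 and 0.52). Y6G8.16, Y6G8.15, Y6G8.13 and Y6G8.14 were all lower, Y6G8.15 from 414 counts over the controls to 0 in every knockdown library, at least 131-fold lower, and Y6G8.16 from 4.08 ± 0.38 to 0.054 ± 0.055 CPM (log2 -6.10, and -6.99 without knockdown replicate 1). Of 5 other genes near the target that were looked at, 2 were called lower. Y54G2A.36 fell from 25.4 ± 3.2 to 9.10 ± 2.70 CPM (log2 -1.48, adjusted p = 0.0069), and Y54G2A.50 was lower by 0.80 on the log2 scale (adjusted p = 0.021, and up to 0.117 without any one control library). Y54G2A.19 (log2 -0.52, adjusted p = 0.125, but 0.0333 without knockdown replicate 1 and 0.0313 with the ribosomal RNA covariate), fbxc-45 (log2 -0.41, adjusted p = 0.149) and Y54G2A.16 (log2 0.10, adjusted p = 0.881) were not called.

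Genes with several transcripts were often listed at 0, and lack of expression is argued against as the whole cause: of 21 ribosomal, proteasome and respiratory chain genes with at least 2 RefSeq transcripts, 52.4% were at 0, against 0.7% of 142 with 1 (Fisher's exact test, two-sided, p = 1.04e-10). A candidate explanation is that reads overlapping several transcripts were left out of the counts. Among genes with at least 2 transcripts in both annotations, 71.4% were at 0 in the third with the fewest bases belonging to a single transcript and 28.3% in the third with the most, a difference of 43.1 percentage points. Some genes with 1 RefSeq transcript, such as col-19 and bli-1, were at 0 too, so it would not account for every 0. Of genes with 1 RefSeq transcript, 18.3% were at 0 where they overlap another coding gene and 3.3% where they do not. Beside the target, named genes such as col-36, col-158 and dpy-20 overlap another coding gene, and how reads of these overlaps were counted is not given. The same counting applied to all 6 libraries, so no explanation from the groups of the study was tested.

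The 17 collagens that rose by more than 16-fold did not follow the summed CPM of the other 111 tested collagens. That sum was lower in each knockdown library than in each control (log2 ratio of means -0.656). It includes the 45 collagens already called lower, and sharing of reads with single similar collagens was not tested. A fixed share of the reads of some other collagens therefore cannot be excluded. With the log ribosomal RNA share as a covariate, 17 of the 17 stayed called. That share ran from 0.214 to 1.64% in the controls and from 0.0937 to 2.02% in the knockdown, so the groups overlapped widely. Such a covariate can take away little of a difference between the groups, so this fit does not decide on differences that follow the share. All 1283 called genes stayed called in that fit, so this result is not particular to these collagens. It remains open whether a share of the knockdown animals was at another developmental stage. Knockdown replicate 2 was below the other knockdown libraries in all 17 genes, by a median log2 ratio of -2.53 with an SD of 0.314 over the genes, which a common share of such animals may give but a shared regulation could give as well. An effect of the knockdown itself on these genes was not separated from stage.

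Among called genes 23 had at most 3 counts over the 3 libraries of a group, 16 of them lower and 7 higher in the knockdown. T07G12.3, for example, had 0 counts in the controls and 92, 92 and 90 in the knockdown, at least 96.2-fold higher. Depth does not account for them, as the library totals of the knockdown were 0.936 of those of the controls. Outside Y6G8, the 24 flanking tested genes had a median log2 fold change of -0.102 (quartiles -1 and 0.523, 3 called lower). This argues against a loss, at most of these places, of chromosome stretches that also hold the flanking genes. The flanks were pooled and not examined place by place, so such a loss at a few places cannot be excluded. Neighbours that were themselves among the 23 were left out of the flanks, so the loss of a stretch holding only genes of that set was not tested. For Y6G8, where 4 adjacent genes were lower and all but Y6G8.15 kept between 2 and 4 counts in at least 1 knockdown library, such a loss cannot be told apart from regulation with so few genes. Sequence differences inside these genes between the animals of the groups could also give such values, and as 10 of the 23 were at exactly 0 in a whole group and 13 were not, they cannot be told apart from an effect of the RNAi.

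With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1283 called genes and the highest of the other splits 0, so 1 of the 10 gave as many. For lists the real split passed 8 and the highest other 15, with 6 of the 10 splits passing as many as the real one, and for families the real split passed 12 and the highest other 40, with 10 of the 10 passing as many. Why other splits passed more families was not tested.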
